A study of Thermothelomyces thermophilus ATCC 42464 with 6 samples.

How the data were processed

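RNA sequencing measured transcript levels in Myceliophthora thermophila (Thermothelomyces thermophilus), a heat-loving filamentous fungus that secretes enzymes for breaking down plant cell walls. The labels describe 6 libraries, 3 of the wild type and 3 of a strain lacking Mtclr-2, the gene of a transcription factor. Mycelium grown on glucose was washed and moved to 2% Avicel, a microcrystalline cellulose, for 48 h. Poly(A) RNA was selected with oligo(dT) beads and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the 3 libraries of a strain came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

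The values are FPKM (fragments per kilobase of transcript per M, or 1000000, mapped fragments) as deposited, 1 column per library, each matched to its sample by library name. Per the submitters' processing notes, the tools were fastp 0.18.0, HISAT2, StringTie 1.3.1, RSEM and DESeq2. Their settings and the genome build are not given in the sources used here. Replicates were not pooled. The table holds 2228 genes, and all of them matched NCBI's RefSeq gene table for assembly ASM22609v1, 2226 by locus tag and 2 by symbol. That gene table has 9097 protein-coding genes, so the listed genes equal 24.5% of them. Because the build behind the FPKM values is not named, no coordinates are given. The gene table was used for names, for the order of genes and, within the depth estimate and the distances between neighbours, for gene lengths and ends.

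The table is a selected set. Every gene differed by at least 2.00-fold between the strain means, 1323 lower and 905 higher in the deletion strain. The genes stood in order of the ratio of mean FPKM, with a mean of 0 replaced by 0.001, in 100.0% of consecutive positions. The rule that selected them is not given in the sources used here. Genes outside the table were not analysed here, so nothing is said of which genes kept their level. A count of changed genes restates the selection, and adjusted p-values over these genes describe the spread between libraries and are not an independent discovery of the genes.

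Depth is not stated with FPKM, so it was estimated from the low values. Where a gene has no intron, FPKM times annotated length in kilobases is a whole multiple of 1 fragment per M. In each library the step was sought on which most products under 0.5 fell, within 1% of 1 to 4 steps. In the 3 wild-type libraries 35 of 94, 26 of 79 and 21 of 90 values fell on the best step, against a median of 2 over the steps tried. In the 3 deletion libraries 12 of 53, 10 of 46 and 13 of 43 did, against a median of 1. Most low values thus fell off the best step. That step was the best of many tried, so some excess over the median is built in. Steps were sought only within a preset range, so no depth outside it could be found. The depths are therefore rough. The estimates were 13.98, 15.68 and 16.63 M fragments for wild-type replicates 1 to 3, and 16.81, 13.09 and 14.23 M for deletion replicates 1 to 3. At such depths 1 FPKM on a gene of the median annotated length, 1.65 kb, stands for 22 to 28 fragments. Such fragment numbers are upper estimates for genes with introns. Intervals made from them cover counting error only, and are too narrow where the true number is lower.

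Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend over expression, two-sided, and Benjamini-Hochberg adjustment over the 2106 genes whose mean FPKM over all 6 libraries was at least 1. Fold changes on this scale understate the change of low genes. Adjusted p-values below are from this test with a threshold of 0.05. The design fixed before the data were examined divided FPKM by median-of-ratios factors. Such factors need mostly unchanged genes. On this table they came to 1.424, 1.412 and 1.431 for the wild-type libraries and 0.697, 0.698 and 0.714 for the deletion libraries, because the median listed gene was lower in the deletion strain. FPKM as deposited, until then an alternative, was therefore reported instead, a change made after seeing the table, and the planned factors are given as an alternative. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. Single values were compared by an exact permutation test, which with 3 against 3 libraries cannot go below p = 0.1.

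The test was checked on simulated data built from the real means and spreads of the 2106 genes, with 200 genes changed. It recovered 84 of 100 genes changed 1.5-fold and 96 of 100 changed 2-fold, and called 13 of 1906 unchanged genes. The simulated noise was normal and most simulated genes were unchanged, whereas the listed genes were all selected for a difference. These rates therefore do not carry over to the calls reported here.

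Before the data were examined, 22 gene lists had been fixed as rules on annotated product text, with 1 list of 19 loci recalled from published work on this fungus. Neither the table nor the gene table holds product text, so only the list of loci could be used. It was tested with camera (preset correlation 0.01), with an estimated correlation and with fry. The names and enzyme classes of these loci were recalled from that work and are unverified: neither the files nor the gene table gives them, except as follows. Only 6 genes of the gene table have a symbol other than the locus tag. One of them, cbdA, is on a locus recorded beforehand as a cellobiose dehydrogenase. The 7 loci of the list outside the table, among them those recorded for Mtclr-2 and Mtbgl1, were not analysed here. The deletion could therefore not be checked on the targeted gene.

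Genes are named by a rule fixed beforehand. They are the loci of the list, the 8 largest falls and 8 largest rises with an adjusted p under 0.05, no overlap between strains and a mean of at least 10 FPKM in the higher strain, and the 2 most abundant members and the most changed member of each tested list. Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or a mean of at least 5 FPKM), the scaling (planned factors, a common sum of 1 M, quantile normalization), the variance model, a replicate block, the set test and leaving out each library. Libraries with the same replicate number did not deviate together: the correlations of their deviations from the strain means were -0.005, 0.031 and 0.082.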

Results

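Transcript levels were compared between the wild type and a strain lacking Mtclr-2 after 48 h on 2% Avicel, with 3 libraries per strain. The question, as the series states it, was which genes the transcription factor MtCLR-2 regulates when the fungus grows on cellulose, with cellulase genes and the genes Mtegl2 and Mtbgl1 in its title. The libraries held an estimated 13.98 to 16.63 M fragments in the wild type and 13.09 to 16.81 M in the deletion strain. The deposited table gives FPKM for 2228 genes that all differed at least 2-fold between the strain means. The comparison below is therefore among genes already selected for a difference.

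The correlation of log2(FPKM + 1) over the listed genes was 0.9942 to 0.9967 between libraries of 1 strain and 0.8133 to 0.8168 between strains. Genes at 100 FPKM or more had a median coefficient of variation between replicates of 2.5% in the wild type and 2.8% in the deletion strain, rising to 13.5% and 13.3% for genes at 1 to 10 FPKM. No 2 libraries were copies of each other: squared differences between replicates were 2.97 to 4.38 times the estimated counting noise. In 2214 of the 2228 genes the 3 values of one strain lay wholly above the 3 of the other, a count that restates the selection of the genes, so the 10% that chance gives for unselected genes does not apply.

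Of the listed genes, 1323 were lower and 905 higher in the deletion strain. Of the 2106 genes tested, 1279 fell and 827 rose at an adjusted p under 0.05 (limma), which is 60.7% falling. With the planned median-of-ratios factors the split was 705 falling to 827 rising, 46.0% falling. These factors moved the median log2 change by 0.94. Falls were more numerous among the smaller changes and rises among the larger ones. Among genes with a mean of at least 1 FPKM and values above 0 in both strains, 1150 were lower and 616 higher by 2 to 4-fold. At 4 to 8-fold 99 were lower and 160 higher, and at 8-fold or more 29 were lower and 51 higher. The 1323 lower genes summed to 157299 FPKM in the wild type and 58400 in the deletion strain. The 905 higher genes went from 45729 to 139844 FPKM, so that the sum over the table was 203029 in the wild type and 198245 in the deletion strain.

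**Figure D1:**
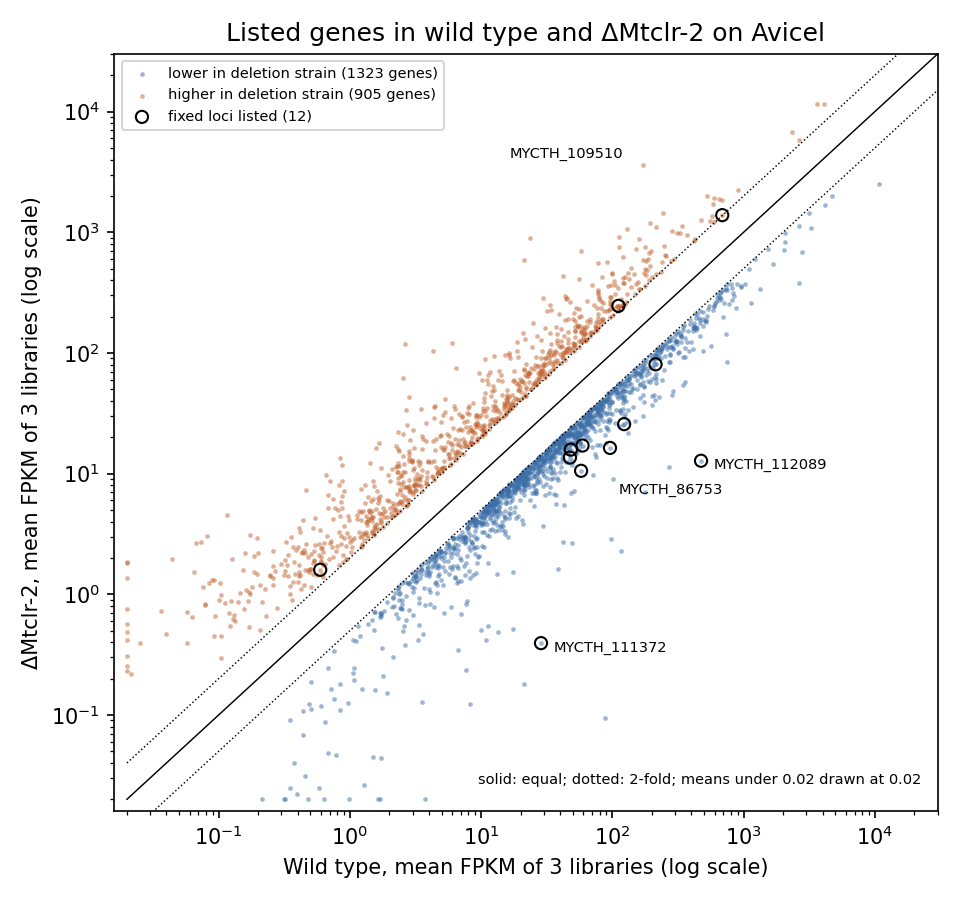
Mean FPKM of the 3 wild-type libraries (horizontal, log scale) against the mean of the 3 ΔMtclr-2 libraries (vertical, log scale) for the 2228 listed genes, 1323 lower and 905 higher in the deletion strain. No gene lies between the dotted 2-fold lines, and circles mark the 12 listed loci fixed beforehand.

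Of 13 loci recorded beforehand as cellulose-degrading enzymes, 9 were in the table, and these 9 were lower in the strain lacking Mtclr-2, by 2.65-fold to 72.6-fold. The other 4 were not analysed here. The 9 comprise 2 cellobiohydrolases, which release cellobiose from the ends of cellulose chains, 2 endoglucanases, which cut within the chains, a β-glucosidase, which splits cellobiose to glucose, and 4 lytic polysaccharide monooxygenases, copper enzymes that cleave cellulose oxidatively. Their summed level went from 1147 ± 18 to 192.7 ± 5.5 FPKM (SD, n = 3), a 5.95-fold decrease. As a share of the FPKM in the table this was 0.565% ± 0.011 in the wild type and 0.097% ± 0.004 in the deletion strain. The 9 were set apart from the 3 loci of the fixed list that rose only after the table was seen, so no test is given for their share. With the planned median-of-ratios factors their falls were smaller. On the log2(FPKM + 1) scale the changes were -0.39 to -4.12 (1.31-fold to 17.4-fold lower), against -1.39 to -5.11 as deposited. The 2.65-fold to 72.6-fold above are ratios of mean FPKM and are not on that scale. These names and classes were recalled from published work on the fungus and could not be checked against the files or the gene table, so what these values say of cellulases depends on unverified assignments.

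MYCTH_86753, recorded as Mtegl2, an endoglucanase of the title, fell from 95.87 ± 1.15 to 16.3 ± 0.70 FPKM, a log2 change of -2.48 ± 0.05 (SE, limma adjusted p = 1.37e-11). The other endoglucanase, MYCTH_111372 (eg1), fell from 28.6 ± 1.94 to 0.394 ± 0.155 FPKM, where the deletion value rests on an estimated 27 fragments over 3 libraries. The counting interval of its 72.6-fold decrease is 49.9 to 110.2-fold (95%, exact Poisson). The cellobiohydrolase loci MYCTH_109566 (cbh1) and MYCTH_66729 (cbh2) also fell, from 47.5 ± 1.37 to 13.6 ± 1.87 FPKM and from 213.1 ± 7.09 to 80.5 ± 2.96 FPKM. By the ratio of mean FPKM these falls were 3.50-fold and 2.65-fold. On the log2(FPKM + 1) scale they were -1.74 and -1.39 as deposited, against -0.77 and -0.39 with the planned factors. The β-glucosidase locus MYCTH_115968 (gh1-1) fell 4.78-fold, from 122.8 ± 0.72 to 25.7 ± 1.15 FPKM.

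Among the 4 lytic polysaccharide monooxygenase loci, MYCTH_112089 was both the most abundant and the most changed, at 473.7 ± 8.50 FPKM in the wild type and 12.8 ± 0.38 in the deletion strain, a 37.1-fold decrease (log2 change -5.11 ± 0.04 SE, limma adjusted p = 7.05e-14). MYCTH_92668 fell 5.47-fold from 57.7 ± 5.41 FPKM, MYCTH_80312 fell 3.47-fold from 59.2 ± 2.27 FPKM, and MYCTH_79765 fell 3.05-fold from 48.2 ± 2.14 FPKM.

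The other 3 listed loci of the fixed list were higher in the deletion strain. MYCTH_2303011, recorded as the protease gene alp-1, rose from 687.1 ± 4.54 to 1386 ± 30.6 FPKM, 2.02-fold. Of 2 loci recorded as cellodextrin transporters, names as unverified as those of the enzyme loci, MYCTH_114107 rose 2.21-fold from 111.1 ± 3.76 to 245.5 ± 7.34 FPKM. MYCTH_43941 rose at a low level, from 0.594 ± 0.096 to 1.59 ± 0.51 FPKM (limma adjusted p = 0.00384). With the planned median-of-ratios factors these rises were larger. On the log2(FPKM + 1) scale they were 2.03, 2.15 and 1.18 in the order given, against 1.01, 1.14 and 0.69 as deposited. The plot of the fixed loci shows the libraries of each strain apart at every locus.

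**Figure D2:**
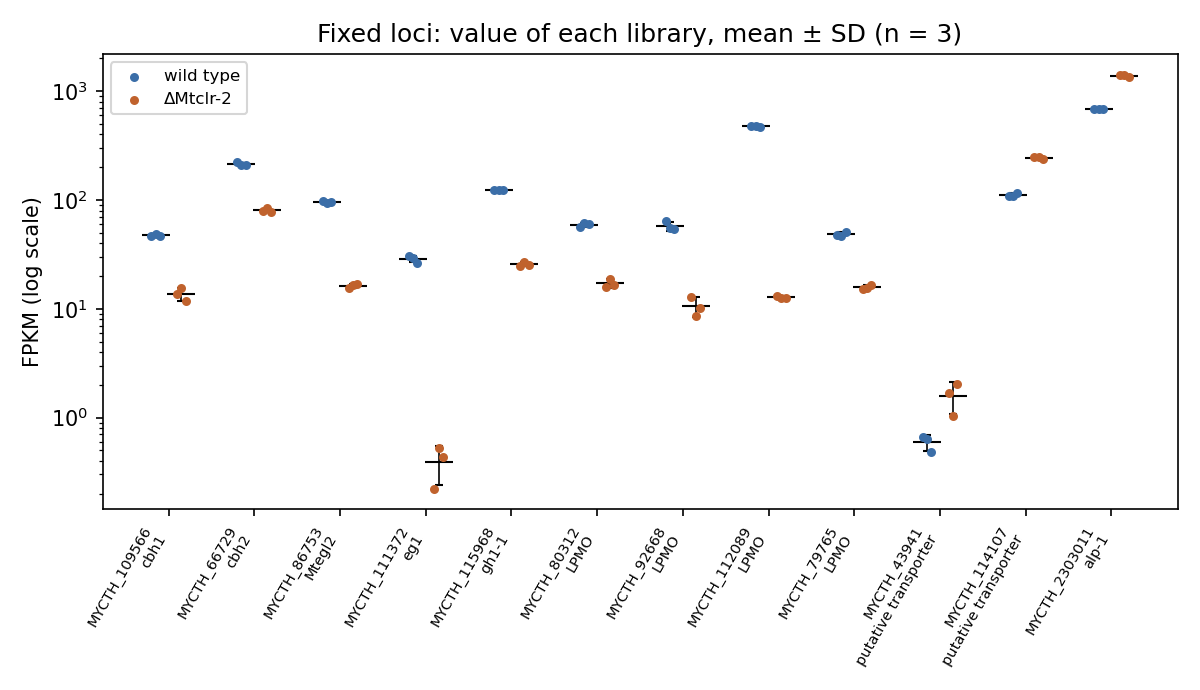
FPKM (vertical, log scale) of each library at the 12 listed loci fixed beforehand, with wild type in blue, ΔMtclr-2 in orange and black bars for mean ± SD (n = 3). The first 9 loci, recorded as cellulose-degrading enzymes, are lower in ΔMtclr-2 and the last 3 are higher.

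As a whole the 12 loci, 9 lower and 3 higher, had a median log2 change of -1.74 and a mean of -1.68. All 12 passed the test both over all genes and adjusted over the list alone. In the test over all genes, however, all 2106 tested genes passed, having been selected for a difference. Passing therefore does not set the list apart. Against the other listed genes, of which most also fell, the list did not stand apart (limma camera p = 0.137, p = 0.192 with an estimated correlation). Its share of the FPKM in the table was 0.958% ± 0.010 in the wild type and 0.921% ± 0.030 in the deletion strain (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give), a difference of -0.037 percentage points. It turned to 0.03 points without the 10 most abundant genes in the sum, and was -0.02 points without deletion replicate 3. The 9 enzyme loci alone, a subset taken after seeing the table that leaves out the 3 loci that rose, had a median log2 change of -2.21 and lay below the other listed genes with the preset correlation (camera p = 0.00419) but not with an estimated one (p = 0.0543). With an estimated correlation the p was 0.0304 under the planned factors and 0.0494 without the filter, and over the threshold under the other alternatives. For 9 or more lower genes among the 12 of the fixed list, from a table in which 59.4% of genes are lower, the exact hypergeometric p is 0.212 (one-sided), which does not pass the threshold. fry, which tests whether the list moves at all and does not compare it with other genes, gave p = 1.52e-08 for the 12 loci. Every listed gene was selected for a difference, so a small p from fry was largely set beforehand and is no support for the list.

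Ranked on the log2(FPKM + 1) scale among genes at 10 FPKM or more in one strain, the largest fall was at MYCTH_52068, from 88.01 ± 3.60 to 0.094 ± 0.105 FPKM, with a log2 change of -6.35 ± 0.10 (SE, limma adjusted p = 2.76e-12). Its deletion value rests on an estimated 6 fragments, so its 933.0-fold decrease has a counting interval of 428.7 to 2542.4-fold. The 6 is an upper estimate if the gene has introns, and fewer fragments would widen the interval. MYCTH_97137 fell 50.3-fold from 115.3 ± 4.51 FPKM, and MYCTH_51545 fell 33.8-fold from 97.95 ± 1.25 FPKM. MYCTH_2309658 and MYCTH_2313136 fell 25.1-fold and 23.8-fold, from 176.6 ± 5.30 and 269.5 ± 1.23 FPKM. MYCTH_84297 fell from 21.0 ± 0.63 to 0.182 ± 0.170 FPKM, 115.6-fold with a counting interval of 64.6 to 231.7-fold from an estimated 11 fragments. MYCTH_112089 and MYCTH_111372, described above, complete the 8 largest falls on this scale. By the ratio of mean FPKM the order differs, as genes outside these 8, chosen after their values were seen, show. MYCTH_55803 fell 34.3-fold from 17.6 ± 1.48 FPKM, further than MYCTH_51545, MYCTH_2309658 and MYCTH_2313136. MYCTH_33936 and MYCTH_2302958 fell 27.5-fold and 25.9-fold, further than MYCTH_2309658 and MYCTH_2313136. MYCTH_2022110 fell 24.0-fold, further than MYCTH_2313136. Of the 8 largest falls, the 6 other than MYCTH_112089 and MYCTH_111372 have no product name in the tables used.

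On the same scale the largest rise was at MYCTH_2303328, from 23.7 ± 0.59 to 892.7 ± 50.97 FPKM, a log2 change of 5.18 ± 0.05 (SE, limma adjusted p = 1.18e-13). By the ratio of mean FPKM, MYCTH_2308271 rose further, 44.9-fold against 37.7-fold. MYCTH_109510 reached the highest level of the 8 largest rises, 3639 ± 22.8 FPKM against 171.2 ± 7.74 in the wild type, 21.3-fold. MYCTH_2095639 rose 27.5-fold to 585.4 ± 38.6 FPKM and MYCTH_2314878 rose 12.2-fold to 698.0 ± 18.5 FPKM. MYCTH_2308271, MYCTH_2313202, MYCTH_80109 and MYCTH_94171 were under 7 FPKM in the wild type and rose to 118.1 ± 3.99, 104.0 ± 2.51, 62.2 ± 4.34 and 119.7 ± 7.79 FPKM. These 8 genes carry only a locus tag.

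The most abundant listed genes changed in both directions. Chosen after their values were seen, MYCTH_2310279 was the most abundant in the wild type, at 10696 ± 33.95 FPKM, and fell 4.27-fold to 2502 ± 64.3 FPKM. MYCTH_2304256 and MYCTH_2315910 fell 2.36-fold and 2.47-fold, from 4686 ± 23.7 and 4149 ± 15.9 FPKM. MYCTH_2307990 and MYCTH_110028 were the most abundant in the deletion strain, at 11520 ± 172.0 and 11493 ± 115.4 FPKM, up 2.79-fold and 3.17-fold. MYCTH_2315548 rose 2.90-fold to 6780 ± 252.8 FPKM. Of the 25 listed genes with a mean of at least 1000 FPKM, 13 were lower and 12 higher in the deletion strain. Both genes listed under a symbol, phy1 and cat1, also chosen after their values were seen, fell, phy1 by 2.17-fold from 21.8 ± 1.70 FPKM and cat1 by 2.07-fold from 134.7 ± 3.93 FPKM.

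Of the genes that could not be compared by a ratio, 7 were listed at 0 in all 3 wild-type libraries and 7 at 0 in all 3 deletion libraries. The locus recorded for Mtbgl1, the other gene of the title, was not analysed here, nor was that of Mtclr-2.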

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

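The use of FPKM as deposited was settled after seeing the table; the other settings here were fixed before. With the planned median-of-ratios factors, 1532 genes passed in place of 2106, with 705 lower in place of 1279, and 50 genes changed sign. Those that passed with a 2-fold or larger change on the log2(FPKM + 1) scale were 924 in place of 1732. By the ratio of mean FPKM as deposited, every listed gene differed at least 2-fold. The construction of the planned factors shows the cause: the median of genes that all changed is taken as unchanged. The fixed list then passed against the other genes, so that 1 list passed in place of 0, with a median log2 change of -0.76. By limma's camera its adjusted p was 0.0121, or 0.0839 with an estimated correlation, which ends the call. With fry 1 list passed as well, an outcome largely set by the selection of the genes. Under the other alternatives with the preset correlation, leaving out each library included, its camera p was 0.0704 to 0.153. Leaving out the 10 most abundant genes from the sum reversed the change in the share held by the fixed list. It went from -0.037 to 0.03 percentage points (exact permutation p = 0.3). The list itself summed to 1945.5 FPKM in the wild type and 1825.8 in the deletion strain either way. The reversal therefore came from the total it was divided by. What set the levels of those 10 genes was not tested. Leaving out 1 library gave -0.046 to -0.02 points. The 26 named genes gave 413 values under alternatives, the planned factors and the replicate block included, and these kept direction and side of the threshold. The named genes were taken from genes already selected for a difference, so this outcome was largely set by the selection. The 3 further values were not to be had, because MYCTH_43941 falls below the filter at a mean of 5 FPKM and without deletion replicate 1 or 3. The planned factors moved the log2 changes of the named genes up by 0.50 to 1.02, leaving the 9 enzyme loci lower by 1.31-fold to 17.4-fold on the log2(FPKM + 1) scale. Leaving out 1 library gave 2089 to 2110 changed genes. The replicate block left 2106 changed genes, 1279 lower and 827 higher, and changed no call. The replicate numbers are shared numbers only, since not every wild-type library deviated most like the deletion library with its own number. Genes under 1 FPKM varied most between replicates, with a median coefficient of variation of 45.5% in the wild type and 39.4% in the deletion strain. How much of this came from depth was not tested.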

Other observations

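Genes that lie next to each other in the RefSeq gene order often changed together. In a run of 5 consecutive genes lower in the deletion strain, the endoglucanase locus MYCTH_111372 stands next to MYCTH_80276, which was at 130.1 ± 2.54 FPKM in the wild type and 26.8 ± 1.35 in the deletion strain (SD, n = 3). That run includes MYCTH_2305390, at 0.453 ± 0.556 FPKM in the wild type and 0.031 ± 0.054 in the deletion strain. It was below the filter for testing, and its values overlapped between strains. In a run of 5 consecutive higher genes, MYCTH_2305886 went from 42.3 ± 1.10 to 432.4 ± 5.92 FPKM and MYCTH_2305890 from 44.4 ± 2.22 to 281.6 ± 3.45 FPKM. A run of 4 lower genes ends with MYCTH_2297132 and MYCTH_2297133, which went from 88.2 ± 3.52 to 20.7 ± 6.37 FPKM and from 359.9 ± 4.73 to 57.4 ± 3.96 FPKM. In that run MYCTH_2297131, at 3.71 ± 3.10 and 0.818 ± 0.563 FPKM, overlapped between strains. These genes were chosen after their values were seen. Runs and pairs used the direction of every listed gene, including the 122 with a mean under 1 FPKM. The table holds 23 runs of 4 or more genes of one direction, against a median of 9 and at most 14 in the central 95% when directions were shuffled among the listed genes 1000 times.

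What each explanation predicts for pairs at least 1 kb apart and for pairs with 1 gene between was written before the results were seen; the other counts had no written prediction. Of 657 pairs of adjacent listed genes, 498 (75.8%) went the same way, against a median of 51.8% over 10000 shuffles of direction (permutation, one-sided p = 0.0001, the smallest these shuffles can give). Reads shared between genes that abut by their RefSeq ends do not account for the whole pattern. Of the 265 pairs with annotated ends at least 1 kb apart, 71.7% went the same way, above the central 95% of shuffles, which reaches 57.7%. The gene models behind the FPKM values are not named, so longer models could still share reads in these pairs. Sharing of reads also remains open for the 392 closer pairs, of which 78.6% went the same way. Regulation of neighbouring genes together is a hypothesis that stays open. Pairs with 1 gene between them went the same way in 61.4% of 572 cases (central 95% of shuffles up to 55.8%), but agreement of adjacent genes would by itself give a raised share where the gene between is also listed. Where that gene was not listed, a split chosen after the result was seen, the share was 58.3% of 369 pairs (central 95% of shuffles up to 56.9%, one-sided permutation p = 0.007), against 136 of 203 pairs where it was. With 4, 9 and 19 genes between the shares were 53.5%, 55.9% and 51.9% (one-sided permutation p = 0.2, 0.03 and 0.5). A regional bias such as GC content could also raise these shares and was not tested, as no genome was used here.

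Listed genes were also next to each other more often than a random set of as many genes, in 657 pairs against a median of 546 (permutation, one-sided p = 0.0001, the smallest that 10000 shuffles can give). The random sets were drawn from all 9097 protein-coding genes of the gene table, whether or not they were expressed. Levels of genes outside the table were not analysed here. Whether listed genes adjoin more often than expressed genes in general was therefore not tested. The share of lower genes was 57.2% to 63.9% across the 7 chromosomes.

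The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2106 genes and the highest of the others 0, on genes that the authors selected with the real split. For the fixed list, 10 of 10 splits, the real one included, gave a camera p as small as the real 0.137. The smallest of the others was 6.41e-04. Every other split has unequal numbers of wild-type and deletion libraries on each side, so it still carries part of the strain difference. The other splits therefore give no chance level for the list, and nothing is concluded from their p-values.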
